A study of Rattus norvegicus with 14 samples.

How the data were processed

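Gonads of fetal rats were profiled on 14 single-channel Affymetrix rat expression arrays, 1 per RNA sample. The samples formed 7 groups of 2: testis and ovary at embryonic days 13, 14 and 16 (E13, E14 and E16), and E13 testis kept in organ culture for 3 days. Per the labels' protocols, every RNA sample was a pool of 20 to 40 gonads extracted with Trizol, the 2 pools of a group were independent, and biotin-labelled target was made by the standard Affymetrix procedures. The cultured testes lay on filters floating on CMRL 1066 medium with insulin, transferrin and albumin, which was renewed on day 2.

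The deposited values were intensities on a linear scale, 1 value per probe set and array; a probe set is a group of short probes for 1 transcript. The software that summarised the probes, its version and any filter are not given in the sources used here. The values themselves showed that each array had been scaled to a common level: the mean after trimming 2% of the probe sets at each end was 125 in all 14 arrays. Of 15923 probe sets, 57 Affymetrix controls were left out of the tests, which left 15866. Among all values, 27 were 0.

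Probe sets were named through the platform annotation supplied with the values. It gave 12783 of the tested probe sets 1 gene symbol, 312 several and 2771 none, and only probe sets with 1 symbol were named. Of these, 12748 gene identifiers were found in a RefSeq gene table of assembly GRCr8, which changed 0 symbols, and the named probe sets stood for 10411 genes. That table served for names alone. No genome build was named for the array and no genome was used here, so no coordinates are given. Sox9, Dhh, Foxl2, Ddx4, Pou5f1, Stra8 and Ddx3y, which had been chosen as label or cell type checks, had no matching probe set name and are not analysed here.

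Values were analysed as log2(value + 16) without further normalization, since the array medians on this scale lay between 6.24 and 6.41. The offset damps noise of dim probe sets and understates the change of genes with low signals, and every log2 difference is on this scale. Levels are given as the mean of the deposited intensities ± SD over the 2 arrays of a group. A model with the 7 groups was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 7 residual degrees of freedom and 4.16 prior degrees of freedom), so that all groups shared 1 estimate of the spread. Each of 13 comparisons was tested with limma's moderated statistic and the Benjamini-Hochberg adjustment over the 15866 probe sets, and an adjusted p under 0.05 was taken as passing. The comparisons were testis against ovary at each age and as the mean over the ages, the sex difference at E16 minus that at E13, the steps between ages in each sex, and cultured E13 testis against fresh E13 and fresh E16 testis. The groups, comparisons, offset, gene lists, rule for named genes and the alternatives were fixed before the data were examined; 2 alternatives and some tests of explanations were added later and are marked as such.

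In each of the 8 main comparisons, the genes named were the 10 with the largest rise and the 10 with the largest fall among probe sets with 1 established symbol that passed and whose arrays did not overlap between the groups (for the mean over ages, the same direction at all ages). Up to 2 members per direction of each gene list with the smallest p, and a set of label and cell type checks, were named as well. A gene with several probe sets is given by the one with the highest mean over all arrays, and disagreement is stated. Copies of near-identical sequence, such as the Hsd3b family, Eci2 and Eci3, the metallothioneins, Cyp11b1 and Cyp11b2, and the globins, can share probes, so their values are uncertain between copies.

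For gene groups, 22 lists with 364 symbols were fixed: Sertoli cell; steroidogenesis and fetal Leydig cell; cholesterol synthesis; pre-granulosa and ovary; germ cell; meiosis; cell cycle; extracellular matrix; smooth muscle and peritubular cell; hedgehog signalling; retinoic acid metabolism; neurotrophin; hypoxia and glycolysis; stress and immediate early; endothelium; red blood cell; macrophage and white blood cell; mesonephros and kidney; adrenal; neuron; Y-linked genes with Xist; and cytosolic ribosomal protein. The 21 lists with at least 3 measured genes were tested with camera from limma at its preset correlation of 0.01, on 1 probe set per gene, with the Benjamini-Hochberg adjustment over lists within a comparison. Camera with an estimated correlation between genes, and fry, which asks whether the genes of a list moved on balance in 1 direction, were run beside it. Members that passed were counted after adjustment over all probe sets and also adjusted over the list alone.

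Chip batches (8) and chip periods (3) were inferred from the form of the array labels and are not known to match actual hybridisation batches. Batches held different mixes of groups, so each comparison was repeated with chip period as a block and, where a period held arrays of both groups, within that period. Change in culture was compared with change in vivo by correlation and covariance across probe sets. Both changes share the E13 testis arrays, so 100 simulations of unchanged groups that share those arrays gave the values reached without an effect.

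The alternatives were an offset of 1, quantile normalization, probe sets with a mean signal above the median, an intensity-dependent prior in eBayes, the replicate number as a block, chip period as a block, chip batch as a random block, and leaving out each array in turn. When an array is left out, the remaining array of its group is assumed to vary like the other groups. Leaving out 4 arrays whose Xist signal went against their label, and taking the changes in culture and in vivo from separate E13 testis arrays, were alternatives chosen after seeing the data. The scripts were tested on simulated data of 15866 probe sets with 100 changed at each of 2 sizes. With log2 changes of 1 and 2, 35% and 92% were recovered for testis against ovary at E13, 37% and 93% at E16, 78% and 100.0% for the mean over ages, and 39% and 91% for cultured against fresh E13 testis. Between 3% and 6.3% of the calls fell on unchanged probe sets. The simulated noise was independent between arrays and probe sets, without chip batch or period effects, so recovery in the real data may differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.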

Results

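The fetal gonad starts out alike in both sexes and then becomes a testis or an ovary. To follow this step, RNA of rat testes and ovaries was measured at E13, E14 and E16, together with E13 testes after 3 days in organ culture. There were 2 arrays per group and 14 in all, each from an independent pool of 20 to 40 gonads. The small number of arrays limits the precision of every value below. Array medians lay between 59.5 and 69.1 intensity units. The 2 arrays of a group correlated at r = 0.949 (E14 ovary) to 0.982 (E13 ovary) across probe sets, and between 0.84% (E13 ovary) and 5.17% (E14 ovary) of probe sets differed at least 2-fold between them.

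Sry, the Y-linked gene that starts testis formation, read 163 and 185 in the E13 testis arrays and at most 28.7 in the ovary arrays. Amh, the Sertoli cell hormone that removes the Müllerian ducts, read 477 to 1093 in the E14, E16 and cultured testis arrays and at most 38.5 in any ovary array. Xist, the RNA that coats the inactive X chromosome of female cells, did not follow the labels in the same way. It read 224 to 672 in the ovary arrays at E13 and E14, but 152 and 12.8 at E16. In testis it read under 5 in 5 arrays, 36.2 in E13 replicate 1, 269 in E14 replicate 1 and 151 in cultured replicate 1. Counts of genes are therefore also given without the 4 arrays E13 testis replicate 1, E14 testis replicate 1, cultured testis replicate 1 and E16 ovary replicate 2, a choice made after seeing the data.

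RNA quality and batch also set some arrays apart. The ratio of the 3′ to the 5′ actin probe sets, which grows as RNA degrades, was 3.34 in E16 ovary replicate 1 and 2.97 in cultured testis replicate 2, against 1.47 to 2.13 elsewhere. These 2 arrays are the only ones left of their groups in the counts without the 4 arrays named above. The first principal component held 24.7% of the variance. Along it the 4 ovary arrays of chip period 3 scored 22.7 to 36, the ovary arrays of chip period 1 scored -4.0 and 1.7, and all testis arrays scored 3.0 or less. Most arrays correlated best with an array of another group and not with their own replicate. In 2 cases that array was of the other sex. E14 ovary replicate 2 correlated more with E14 testis replicate 2 of its own chip batch (r = 0.967) than with its replicate (r = 0.949). E13 testis replicate 1 correlated more with E13 ovary replicate 2 of its own chip period (r = 0.966) than with its replicate (r = 0.958).

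**Figure D1:**
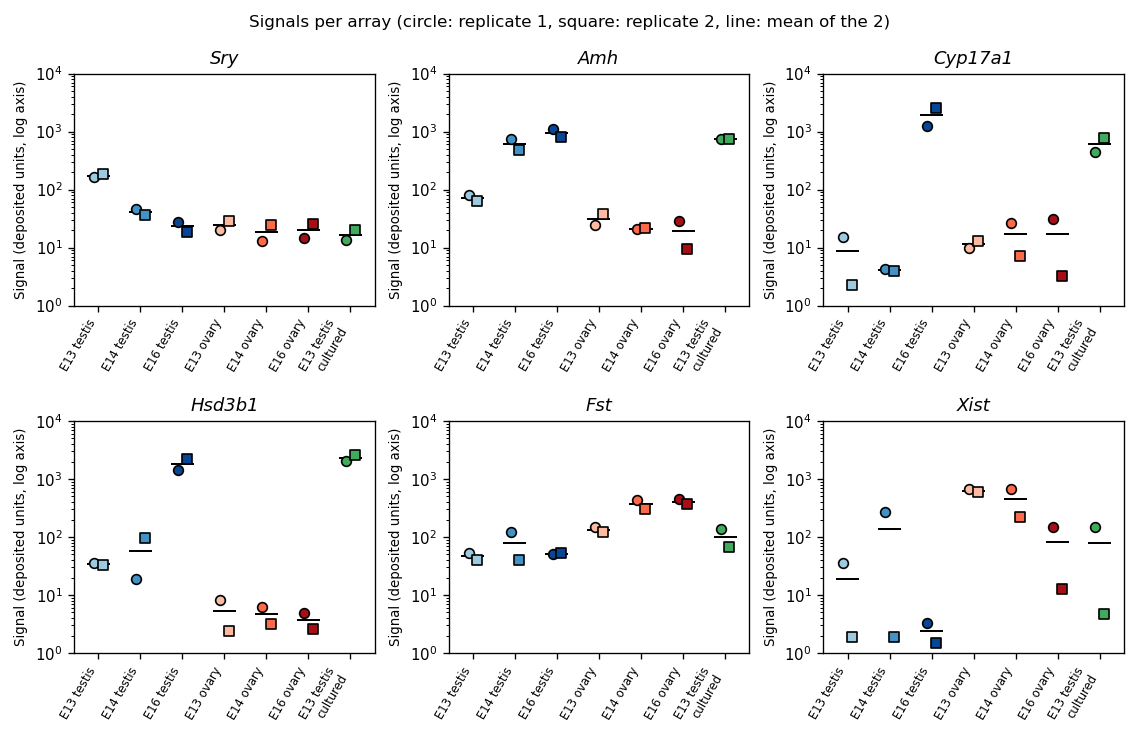
Signals of 6 genes in deposited units on a log axis, by group. Circles are replicate 1, squares replicate 2 and lines the mean of the 2 arrays. Sry stood apart in E13 testis, Amh was high in testis from E14 and in culture, Cyp17a1 and Hsd3b1 were high in E16 and cultured testis, Fst was higher in E16 ovary than in E16 testis, and Xist varied within groups.

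The comparison of testis with ovary at E13 asks which genes differ at the start of sex determination. Sry stood at 174 ± 15.6 (SD, n = 2) in testis and 24.4 ± 6.1 in ovary (log2 2.24, adjusted p = 0.0159 by limma). The only other probe set that passed, for Angel2, stood at 7.8 ± 0.8 in testis and 69.6 ± 6.1 in ovary (log2 -1.85, adjusted p = 0.0159). Amh did not yet pass, at 71.7 ± 11 in testis and 31.5 ± 9.9 in ovary (log2 0.90, adjusted p = 0.516). Of 12 measured pre-granulosa and ovary genes, 0 passed over all probe sets, while Fst (log2 -1.26) and Bmp2 were lower in testis when adjusted over the list alone. As a set they were lower in testis (camera, adjusted p = 0.0198), a call that was lost with chip period as a block (adjusted p = 0.107) and with an estimated correlation (adjusted p = 0.763). No other list was called. With chip period as a block, 2 probe sets passed, Sry (adjusted p = 0.041) among them and Angel2 not (adjusted p = 0.0615). Within chip period 3 both kept their direction; here and below, the arrays within a period or batch are part of those that made the calls, so that a kept direction is no independent check. Without E13 testis replicate 1 or 2, E13 ovary replicate 1 or 2, or the 4 arrays with discordant Xist, the count was 0 by limma against 1236 probe sets at an unadjusted p under 0.05 in the full set (793 by chance), and without either E16 testis array it was 1.

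At E14, the day after, the testis stood out by Amh and by a small set of further genes. Amh reached 618 ± 200 (SD, n = 2) in testis against 21.4 ± 1.1 in ovary (log2 4.05, adjusted p = 0.000422 by limma). It passed in all 14 fits that left out 1 array. Also higher in testis were Tsx (log2 2.89), Mia (log2 2.50), Aldh1a1, a retinaldehyde dehydrogenase (388 ± 96 against 69.1 ± 25.9, log2 2.26, adjusted p = 0.032), Cst8 (log2 2.08), Mgst2 (log2 1.88), Pln (log2 1.80), Aard (log2 1.71), Tcf21 (log2 1.69) and Csrp2 (log2 1.65). Lower in testis were Cyp1b1 (224 ± 99.5 against 932 ± 63.6, log2 -2.04, adjusted p = 0.0177), Apoc4 (log2 -2.01), Cd74 (log2 -1.98), Eci2 (log2 -1.87), the matrix protein gene Postn (log2 -1.74), Amhr2, the receptor of Amh (log2 -1.64), Lzts1 (log2 -1.63) and Etnk1 (log2 -1.37). A probe set of Ly6l was lower as well, but the 2 others of that gene did not pass.

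In total 22 probe sets passed at E14, 11 in each direction; the count was 11 with an offset of 1 and 93 with chip batch as a random block. Of 18 measured Sertoli cell genes, Amh and Aard were higher in testis and 16 did not pass; adjusted over the list alone, 6 were higher and 1 lower. The list was higher as a set (camera, adjusted p = 0.00303; adjusted p = 0.189 with an estimated correlation). Of 12 pre-granulosa and ovary genes, 0 passed over all probe sets and 4 (Fst, Bmp2, Lgr5 and Cdkn1b) were lower in testis adjusted over the list alone. That list was lower as a set (adjusted p = 2.96e-07; adjusted p = 0.189 with an estimated correlation), with Fst, the activin-binding follistatin, at 79.8 ± 57.1 in testis and 376 ± 94.5 in ovary (adjusted p = 0.0808). The 23 cell cycle genes (adjusted p = 0.0032; adjusted p = 0.266 with an estimated correlation and 0.0675 with chip period as a block) and the 10 smooth muscle genes (adjusted p = 0.0107; adjusted p = 0.189 with an estimated correlation) were higher in testis as sets, with 0 members passing in each. All 22 probe sets kept their direction in the 2 arrays of 1 chip batch. A block for chip period gave 35 calls, 17 of them shared, while Mia, Tcf21, Csrp2, Postn and Etnk1 no longer passed. When 1 array was left out, Etnk1 and Tcf21 lost their call in 13 of 14 fits, Aldh1a1 in 12, Aard, Cd74, Csrp2 and Mgst2 in 11 and Postn in 9. The count was 1 without E14 testis replicate 2, 7 and 9 without E14 ovary replicates 1 and 2, 13 without E16 testis replicate 1 or 2 or E13 ovary replicate 1 or 2, and 0 without the 4 arrays with discordant Xist (limma; 1270 at an unadjusted p under 0.05 in the full set).

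At E16 the genes of steroid hormone synthesis set the testis apart. Hsd3b1, which oxidises pregnenolone to progesterone, stood at 1817 ± 545 (SD, n = 2) in testis and 3.8 ± 1.6 in ovary (log2 6.51, adjusted p = 2.9e-05 by limma). Cyp17a1, which makes androgen precursors, stood at 1899 ± 943 against 17.2 ± 19.7 (log2 5.90, adjusted p = 0.000207). Cyp11a1, the enzyme that cleaves the cholesterol side chain, stood at 833 ± 308 against 37.5 ± 0.7 (log2 3.94, adjusted p = 2.56e-05). Insl3, the Leydig cell peptide needed for descent of the testis (log2 4.55, adjusted p = 0.00312), and Star, which carries cholesterol into mitochondria (log2 2.68, adjusted p = 0.00371), were higher too. Of 13 measured steroidogenesis and Leydig cell genes, 8 were higher in testis, 0 lower and 5 did not pass; adjusted over the list alone, 12 were higher. The list was called with the preset and the estimated correlation (adjusted p = 1.56e-22 and 0.00652).

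Outside steroidogenesis, genes higher in E16 testis than in ovary included Cpa1, a pancreatic-type carboxypeptidase (2357 ± 1166 against 21.9 ± 19, log2 5.97, adjusted p = 2.9e-05), Amh (log2 4.82), Tsx (log2 4.02), Aldh1a1 (log2 3.07) and Svs5 (log2 2.98). Of 18 Sertoli cell genes, Amh, Aard, Inha, Vnn1, Tesc and Krt18 were higher in testis, Ptgds was lower (log2 -1.16, adjusted p = 0.0467), and 11 did not pass; adjusted over the list alone, 9 were higher and 2 lower. The set was called by camera (adjusted p = 5.28e-06; adjusted p = 0.0493 with an estimated correlation). Of 10 smooth muscle genes, Acta2 (log2 1.69), Tagln, Myl9, Tpm1 and Tpm2 were higher and 5 did not pass, with 6 higher adjusted over the list alone (camera, adjusted p = 5.78e-07; adjusted p = 0.00898 with an estimated correlation). The 7 neurotrophin genes were higher as a set (adjusted p = 0.0104; adjusted p = 0.126 with an estimated correlation) with 0 members passing; adjusted over the list alone, Ngfr was higher.

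The E16 ovary had its own higher genes. Ppp2r2b, a regulatory subunit of protein phosphatase, stood at 510 ± 301 (SD, n = 2) in ovary and 16.7 ± 13.7 in testis (log2 -3.94, adjusted p = 0.00312 by limma), and Fst at 408 ± 58.8 against 51.9 ± 0.3 (log2 -2.63, adjusted p = 0.00672). Metallothionein Mt2A (log2 -3.0), the keratin Krt19 (log2 -2.89), the corepressor Tle6 (log2 -2.81), the retinol carrier Rbp4 (log2 -2.76), Eci3 (log2 -2.67), Postn (log2 -2.37) and the kinase gene Prkcz (log2 -2.33) were lower in testis as well. A probe set of Cnr1 passed (log2 -2.28), but the brighter one of that gene did not (log2 -0.09). Of 12 pre-granulosa and ovary genes, Fst and Lgr5, a Wnt-pathway receptor, were lower in testis, 10 did not pass, and 6 were lower adjusted over the list alone (camera, adjusted p = 5.28e-06; adjusted p = 0.126 with an estimated correlation). Wnt4, a signal of ovarian development, stood at 249 ± 229 in ovary and 63.2 ± 19.5 in testis and did not pass (log2 -1.43, adjusted p = 0.389). The 20 hypoxia and glycolysis genes were lower in testis as a set (adjusted p = 0.000581; adjusted p = 0.126 with an estimated correlation), with 0 members passing. Among 10 retinoic acid genes, Aldh1a1 and Crabp2 (log2 1.52) were higher, Rbp4 was lower, 7 did not pass, and 3 were higher and 1 lower adjusted over the list alone; the set was not called (adjusted p = 0.209).

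Over all probe sets, 276 passed at E16, 161 higher and 115 lower in testis, or 143 higher and 138 lower after quantile normalization. The count was 167 with an offset of 1 and 594 with chip batch as a random block. Of the E14 calls, 10 of 11 higher and 11 of 11 lower ones passed at E16 in the same direction (0.11 and 0.08 from independent lists). Of the 276 calls, 89.5% had the same sign at E14, at a median 0.44 of the E16 size, and 70.7% at E13, at a median 0.16. These comparisons share no arrays, but the replicate 1 arrays of E14 and E16 lay in the same chip batch within each sex, so a batch difference between the sexes would enter both and they are not independent. All 276 kept their direction within the chip batch that held both sexes, whose 2 arrays are among the 4 behind the calls. Blocked by chip period, 323 passed, 207 of them shared. Without the 4 arrays with discordant Xist, E16 ovary rests on replicate 1 alone, which lay in a chip period with no E16 testis array. The count was 62 and 103 without E16 testis replicates 2 and 1, 142 and 161 without E16 ovary replicates 1 (the array with an actin ratio of 3.34) and 2, 176 without E13 ovary replicate 1 or 2, and 14 without the 4 arrays with discordant Xist.

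**Figure D2:**
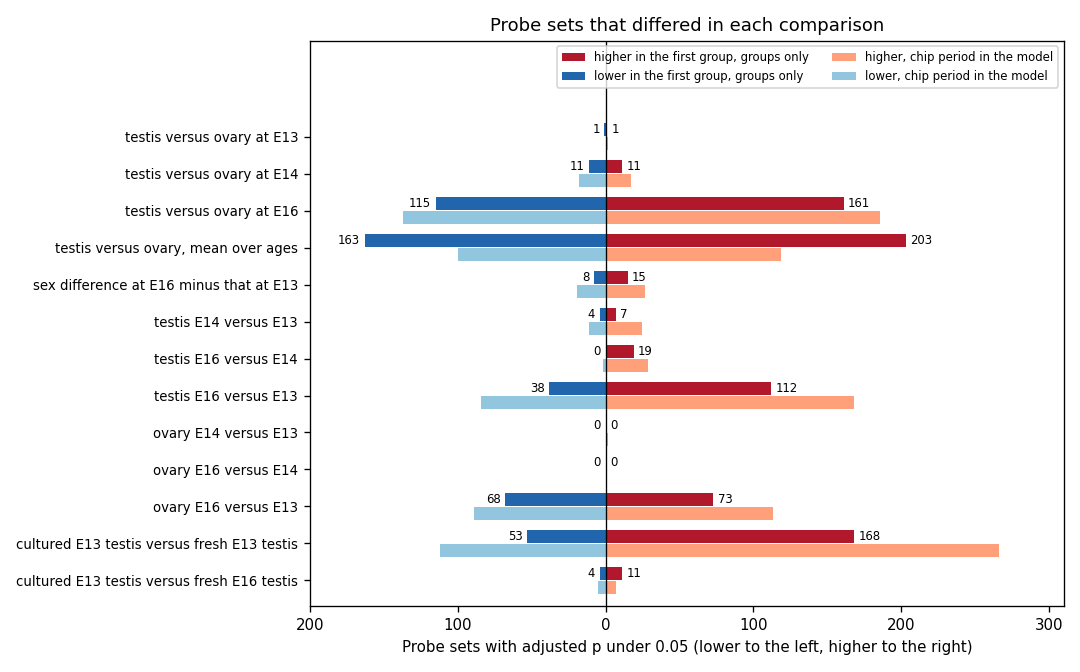
Number of probe sets that passed (adjusted p under 0.05) in each of the 13 comparisons, higher in the first-named group to the right and lower to the left. Dark bars are the model with groups only, pale bars the model with chip period as a block. Testis against ovary rose from 2 probe sets at E13 to 276 at E16.

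Averaged over the 3 ages, Amh, Hsd3b1 and Tsx were among the genes higher in testis, and Ppp2r2b and Fst among those higher in ovary. Over 6 arrays per sex, Amh stood at 548 ± 417 (SD over all ages, n = 6) against 24.1 ± 9.6 (log2 3.25, adjusted p = 1.22e-05 by limma), Hsd3b1 differed by log2 3.12 and Tsx by log2 2.64. Aldh1a1 (log2 1.96), the detoxifying enzymes Mgst2 (log2 1.62) and Gsta1 (log2 1.39), Cst8 (log2 1.54), the transcription factor gene Tcf21 (log2 1.51) and Mia (log2 1.38) were also higher in testis. Higher in ovary were Ppp2r2b (log2 -2.11), Fst (log2 -2.02, adjusted p = 0.00132), Tle6 (log2 -1.67), Cyp1b1 (log2 -1.64), Apoc4 (log2 -1.56), Eci3 (log2 -1.51), Mt2A (log2 -1.47), Eci2 (log2 -1.44), Postn (log2 -1.43) and Amhr2 (log2 -1.39, adjusted p = 0.000188). A probe set of Dusp6 passed, but the brightest one of that gene did not (log2 0.67, adjusted p = 0.225). Xist stood at 388 ± 292 in ovary and 52.3 ± 107 in testis and did not pass (log2 -2.94, adjusted p = 0.0686).

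Over the ages 4 lists differed. The Leydig cell list had 6 of 13 genes higher in testis (10 adjusted over the list alone; camera, adjusted p = 1.42e-10, and 0.0406 with an estimated correlation). The smooth muscle list had Acta2 and Tpm1 of 10 higher (6 adjusted over the list alone; adjusted p = 0.000179, and 0.0406 with an estimated correlation). The Sertoli cell list had 6 of 18 genes higher (8 adjusted over the list alone; adjusted p = 0.000169; adjusted p = 0.0985 with an estimated correlation). The pre-granulosa list had Fst, Bmp2, Lgr5 and Cdkn1b of 12 lower in testis (9 adjusted over the list alone; adjusted p = 4.69e-07; adjusted p = 0.121 with an estimated correlation). In all, 366 probe sets passed, 203 higher and 163 lower in testis, and all had the same direction with chip period as a block, where 219 passed, 150 of them shared. The share of higher calls was 55.5% as deposited and 45.1% after quantile normalization. Without single arrays the count was 242 (E13 testis replicate 2), 150 (E14 testis replicate 2), 232 and 192 (E16 testis replicates 1 and 2), 166 and 146 (E13 ovary replicates 1 and 2), 209 and 815 (E14 ovary replicates 1 and 2) and 220.0 (E16 ovary replicate 1), and without the 4 arrays with discordant Xist it was 48.

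Whether the sex difference itself grew with age was tested as the difference at E16 minus that at E13. It passed for 23 probe sets, 15 that grew towards testis and 8 that shifted towards ovary (8 in all with an offset of 1 and 45 with chip batch as a random block). Cyp17a1 (log2 6.09, adjusted p = 0.00714 by limma), Cpa1 (log2 5.91) and Hsd3b1 (log2 5.25) were the largest towards testis, and Rbp4 (log2 -3.12), Mt2A (log2 -2.85) and Postn (log2 -2.19) towards ovary. Sry shifted by log2 -2.12 (adjusted p = 0.0488), from a sex difference of log2 2.24 at E13 to 0.12 at E16. A block for chip period gave 46 calls, 22 of them shared. The count was 10 and 2 without E13 testis replicates 1 and 2, 5 without E16 testis replicate 2, 5 and 2 without E13 ovary replicates 1 and 2, 12 and 7 without E16 ovary replicates 1 and 2, and 0 (limma, 1030 at an unadjusted p under 0.05 in the full set) without the 4 arrays with discordant Xist.

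In testis, steroidogenic genes rose from E13 to E16. Cyp17a1 rose from 8.9 ± 9.3 to 1899 ± 943 (SD, n = 2; log2 6.22, adjusted p = 0.000317 by limma), Hsd3b1 from 34.5 ± 2.2 to 1817 ± 545 (log2 5.15) and Cyp11a1 from 40.3 ± 1.1 to 833 ± 308 (log2 3.87, adjusted p = 3.14e-05). Mgp, an inhibitor of calcification, rose from 13.5 ± 10.1 to 582 ± 227 (log2 4.33), together with Cpa1 (log2 4.66), Insl3 (log2 4.49), Amh (log2 3.46), Tsx (log2 3.14), the peptidase gene Enpep (log2 3.06, its other probe set 0.22) and the proteoglycan gene Dcn (log2 2.92). Sry fell from 174 ± 15.6 to 23.4 ± 6.9 (log2 -2.28, adjusted p = 0.00169), along with Tle6 (log2 -2.18), the lactate transporter gene Slc16a3 (log2 -2.07), Hoxa5 (log2 -2.05), Mt2A (log2 -1.60), Ldha (log2 -1.54), Errfi1 (log2 -1.51) and Cga (log2 -1.46). Single probe sets of Oprk1 and Ly6l fell while the brightest ones of these genes did not pass.

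By list, 8 of 13 Leydig cell genes rose in testis from E13 to E16 and 5 did not pass (10 rose adjusted over the list alone; camera, adjusted p = 7.84e-22, and 0.0072 with an estimated correlation). Amh, Aard (log2 2.49), Inha, Vnn1, Cldn11 and Tesc rose among 18 Sertoli cell genes (7 rose and 1 fell adjusted over the list alone; adjusted p = 4.04e-05; adjusted p = 0.0567 with an estimated correlation). Of 20 hypoxia and glycolysis genes, Pgk1, Ldha and Eno1 fell, 17 did not pass, and 12 fell and 1 rose adjusted over the list alone (adjusted p = 6.54e-08, and 0.0338 with an estimated correlation). A probe set of Vegfa fell as well (log2 -1.251), while its brightest one did not pass. Of 10 smooth muscle genes Tpm2 rose (5 adjusted over the list alone; adjusted p = 4.04e-05, and 0.0266 with an estimated correlation). A probe set of Tpm1 fell and passed (log2 -0.918), while its brightest one did not pass. Of 5 meiosis genes Sycp3 (log2 1.62) and Stag3 (log2 2.05) rose (3 adjusted over the list alone; adjusted p = 9.64e-05; adjusted p = 0.0643 with an estimated correlation). Of 24 extracellular matrix genes Col6a3 and Dcn rose (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.00725; adjusted p = 0.373 with an estimated correlation).

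Further lists were called in testis between E13 and E16 with 0 members passing over all probe sets, each gene taken by its brightest probe set. Cholesterol synthesis was higher at E16 (17 genes, adjusted p = 0.0141; adjusted p = 0.108 with an estimated correlation). Another probe set of its member Hsd17b7 rose and passed (log2 1.129). Germ cell genes were higher too (5 genes, 1 of them, Tex101, adjusted over the list alone; adjusted p = 0.0486; adjusted p = 0.174 with an estimated correlation and 0.0626 after quantile normalization), as were macrophage and white blood cell genes (13 genes, 1 adjusted over the list alone; adjusted p = 0.0301; adjusted p = 0.108 with an estimated correlation). Mesonephros and kidney genes were lower (9 genes, Lhx1 and Emx2 adjusted over the list alone; adjusted p = 0.0206; adjusted p = 0.149 with an estimated correlation), as were neuron genes (8 genes, Nefm adjusted over the list alone; adjusted p = 0.0279; adjusted p = 0.231 with an estimated correlation). In all 150 probe sets passed, 112 higher and 38 lower at E16, and 94 with an offset of 1. All kept their direction within chip period 1. Blocked by chip period, 252 passed, 128 of them shared. The count was 85 and 36 without E13 testis replicates 1 and 2, 78 and 22 without E16 testis replicates 1 and 2, 96 without E13 ovary replicate 1 or 2, and 6 without the 4 arrays with discordant Xist.

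The 2 shorter steps in testis gave fewer calls: 11 probe sets from E13 to E14 (7 higher, 4 lower) and 19 from E14 to E16 (all higher), or 36 and 31 with chip period as a block, 7 and 7 with an offset of 1 and 20 and 30 with chip batch as a random block. The calls kept their direction in every chip period that held both ages. From E13 to E14 the count was 0 without either E13 testis array (limma; 1141 at an unadjusted p under 0.05 in the full set), 2 without either E14 testis array, 4 without either cultured array and 5 without either E13 ovary array, and without the 4 arrays with discordant Xist it was 0. From E14 to E16 it was 12 and 7 without E14 testis replicates 1 and 2, 7 without E16 testis replicate 2, 12 without either E13 ovary array, and 4 without the 4 arrays with discordant Xist.

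In the ovary, genes of meiosis rose from E13 to E16. Sycp3, a part of the synaptonemal complex that pairs chromosomes in meiosis, rose from 19.9 ± 1.3 to 171 ± 25 (SD, n = 2; log2 2.37, adjusted p = 0.00284 by limma). Of 5 measured meiosis genes, Sycp2, Sycp3 and Stag3 rose, 2 did not pass, and the same number rose adjusted over the list alone (camera, adjusted p = 1.22e-05; adjusted p = 0.148 with an estimated correlation). The rise was not particular to the ovary: Sycp3 and Stag3 also rose in testis (log2 1.62 and 2.05). No meiosis gene was among the probe sets whose sex difference changed between E13 and E16. Mgp rose from 3.4 ± 3.5 to 434 ± 126 (log2 4.52, adjusted p = 0.00187), Mt3 by log2 3.54, Rbp4 by log2 2.88, Mapkapk3 by log2 2.65, Tuba4a by log2 2.29, Enpep by log2 2.27 (its other probe set -0.14), Col6a3 by log2 2.22, Afg2a by log2 2.06 and Stard10 by log2 2.04 (its other probe set 0.04). The chemokine Cxcl12 fell from 1126 ± 27.8 to 188 ± 78.3 (log2 -2.54, adjusted p = 0.00543), with Klk1 (log2 -1.86), Hoxa5 (log2 -1.68), Kcne3 (log2 -1.64), Gucy1b1 (log2 -1.62), Cga, the common subunit of glycoprotein hormones (log2 -1.61), Lpar1 (log2 -1.60) and Crispld2 (log2 -1.60). Probe sets of Dusp6 and Kif26b fell too, while the brightest ones of these genes did not pass (adjusted p = 0.101 and 0.129).

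No list other than meiosis was called in the ovary. Fst stood at 135 ± 16.4 at E13 and 408 ± 58.8 at E16 (SD, n = 2; log2 1.49, adjusted p = 0.125 by limma), and Nr0b1, a repressor of steroidogenic genes, fell (log2 -1.50, adjusted p = 0.024). Over all probe sets 141 passed (60 with an offset of 1), 73 higher and 68 lower at E16, of which 14 higher and 10 lower ones passed in the same direction in testis (0.52 and 0.16 from independent lists). The 2 changes share no arrays but are not independent. The replicate 2 arrays of E16 testis and E16 ovary lay in 1 chip batch, and E13 testis replicate 1 lay in the chip period of the E13 ovary arrays. From E13 to E14 and from E14 to E16 the count in ovary was 0 by limma, against 679 and 975 at an unadjusted p under 0.05 (793 by chance), and 2 and 1 with chip period as a block; the second was 1 without E16 ovary replicate 1. All 141 kept their direction within chip period 3, where E16 ovary was represented by replicate 1 alone, the array with an actin ratio of 3.34. Lpar1 lost its call in 10 and Stard10 in 9 of the 14 fits without 1 array. A block for chip period gave 202 calls, 111 of them shared. The count was 8 and 12 without E13 ovary replicates 1 and 2, 60 and 41 without E16 ovary replicates 1 (the array with an actin ratio of 3.34) and 2, 89 without E14 testis replicate 1 or 2, and 0 (limma, 1691 at an unadjusted p under 0.05 in the full set) without the 4 arrays with discordant Xist.

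The cultured testis was compared with fresh E13 testis to see which genes change when the organ develops in isolation. Genes of steroid hormone synthesis rose: Hsd3b1 went from 34.5 ± 2.2 to 2287 ± 362 (SD, n = 2; log2 5.50, adjusted p = 0.000211 by limma), Cyp17a1 from 8.9 ± 9.3 to 605 ± 237 (log2 4.64, adjusted p = 0.00106) and Cyp11a1 from 40.3 ± 1.1 to 448 ± 56.5 (log2 3.04, adjusted p = 0.000207). Amh rose from 71.7 ± 11 to 738 ± 1.0 (log2 3.11, adjusted p = 0.0008). Mgp (log2 4.54), Aldh1a1 (log2 3.44), the microfibril gene Mfap4 (log2 2.91), the electron donor of the steroidogenic enzymes Fdx1 (log2 2.63) and Dcn (log2 2.60) rose too. Cyp11b1 and Cyp21a1, enzymes of corticosteroid synthesis known from the adrenal cortex, rose from 23.3 ± 2.1 to 262 ± 101 (log2 2.77, adjusted p = 0.0008) and from 16.4 ± 12 to 148 ± 9.0 (log2 2.39, adjusted p = 0.00231). Sry fell from 174 ± 15.6 to 16.8 ± 4.8 (log2 -2.54, adjusted p = 0.0008), with Tle6 (log2 -2.12), Slc16a3 (log2 -1.68), Ybx2, a germ cell RNA-binding protein gene (log2 -1.64), Baiap2l1 (log2 -1.63), Mt2A (log2 -1.62), Hoxa5 (log2 -1.52), Cd74 (log2 -1.49) and Gucy1b1 (log2 -1.34). A probe set of Ly6l fell, but the brightest one did not pass.

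By list, 6 of 13 Leydig cell genes rose in culture and 7 did not pass (10 rose adjusted over the list alone; camera, adjusted p = 6.44e-16, and 0.0121 with an estimated correlation). Among them, Insl3 stood at 255 ± 114 in culture and 28.0 ± 13.9 in E13 testis (SD, n = 2) and did not pass (adjusted p = 0.0527 by limma). Amh, Aard, Clu, Inha, Vnn1, Cldn11 and Tesc rose among 18 Sertoli cell genes (8 rose and 2 fell adjusted over the list alone; adjusted p = 1.46e-05, and 0.0455 with an estimated correlation). Of 17 cholesterol synthesis genes Msmo1 (log2 0.90) and Insig1 (log2 1.07) rose, and 11 rose adjusted over the list alone (adjusted p = 1.22e-07, and 0.0121 with an estimated correlation). A probe set of Hsd17b7 rose too (log2 1.179), while its brightest one did not pass. Of 13 macrophage and white blood cell genes Lyz2 rose (log2 1.14), and 5 rose adjusted over the list alone, the complement genes C1qa, C1qb and C1qc among them (adjusted p = 0.000107, and 0.0217 with an estimated correlation). Of 6 adrenal genes Cyp11b1 and Cyp21a1 rose (4 adjusted over the list alone; adjusted p = 2.2e-06; adjusted p = 0.0534 with an estimated correlation).

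Other lists were called in culture at the preset correlation alone. Extracellular matrix was higher, with Col6a3 and Dcn of 24 rising (2 up and 1 down adjusted over the list alone; adjusted p = 0.00181; adjusted p = 0.335 with an estimated correlation). So was smooth muscle with 0 of 10 passing by the brightest probe set of each gene (Tpm2 adjusted over the list alone; adjusted p = 0.035; adjusted p = 0.118 with an estimated correlation). Other probe sets of its member Tpm1 passed in the opposite direction, as lower in culture (log2 -1.221 and -1.385). Cell cycle was lower with 0 of 23 passing over all probe sets or over the list alone (adjusted p = 0.000319; adjusted p = 0.118 with an estimated correlation). Hypoxia and glycolysis was lower with Slc2a3 down but Pfkp up among 20, and 9 lower and 1 higher adjusted over the list alone (adjusted p = 6.14e-05; adjusted p = 0.0673 with an estimated correlation). A probe set of Pgk1 was lower as well (log2 -1.149), while its brightest one did not pass. Red blood cell genes were lower, with Slc4a1 of 9 passing (adjusted p = 0.0105; adjusted p = 0.429 with an estimated correlation). The 2 cultured arrays differed widely in them: Hbb read 2421 in replicate 1 and 13 in replicate 2. Of 23 stress and immediate early genes Hspb1, Atf3 and Hmox1 rose and Mt2A fell, and the list was not called (adjusted p = 0.083). The hedgehog (3 genes, median log2 0.19, adjusted p = 0.335), endothelium (12 genes, 0.17, adjusted p = 0.466) and cytosolic ribosomal protein lists (13 genes, 0.13, adjusted p = 0.262) were not called here or in the other main comparisons, the 8 in which lists were tested.

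In all 221 probe sets passed in cultured against fresh E13 testis, 168 higher and 53 lower, and 106 with an offset of 1. All kept their direction within chip period 1, where the only cultured array was replicate 2, with an actin ratio of 2.97. Slc16a3 lost its call in 13 and Cd74 in 8 of the 14 fits without 1 array. Blocked by chip period, 378 passed, 181 of them shared. The count was 49 without cultured replicate 2, the array with an actin ratio of 2.97, 82 and 80 without E13 testis replicates 1 and 2, 141 without E14 testis replicate 1 or 2, 129 without E13 ovary replicate 1 or 2, and 5 without the 4 arrays with discordant Xist.

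**Figure D3:**
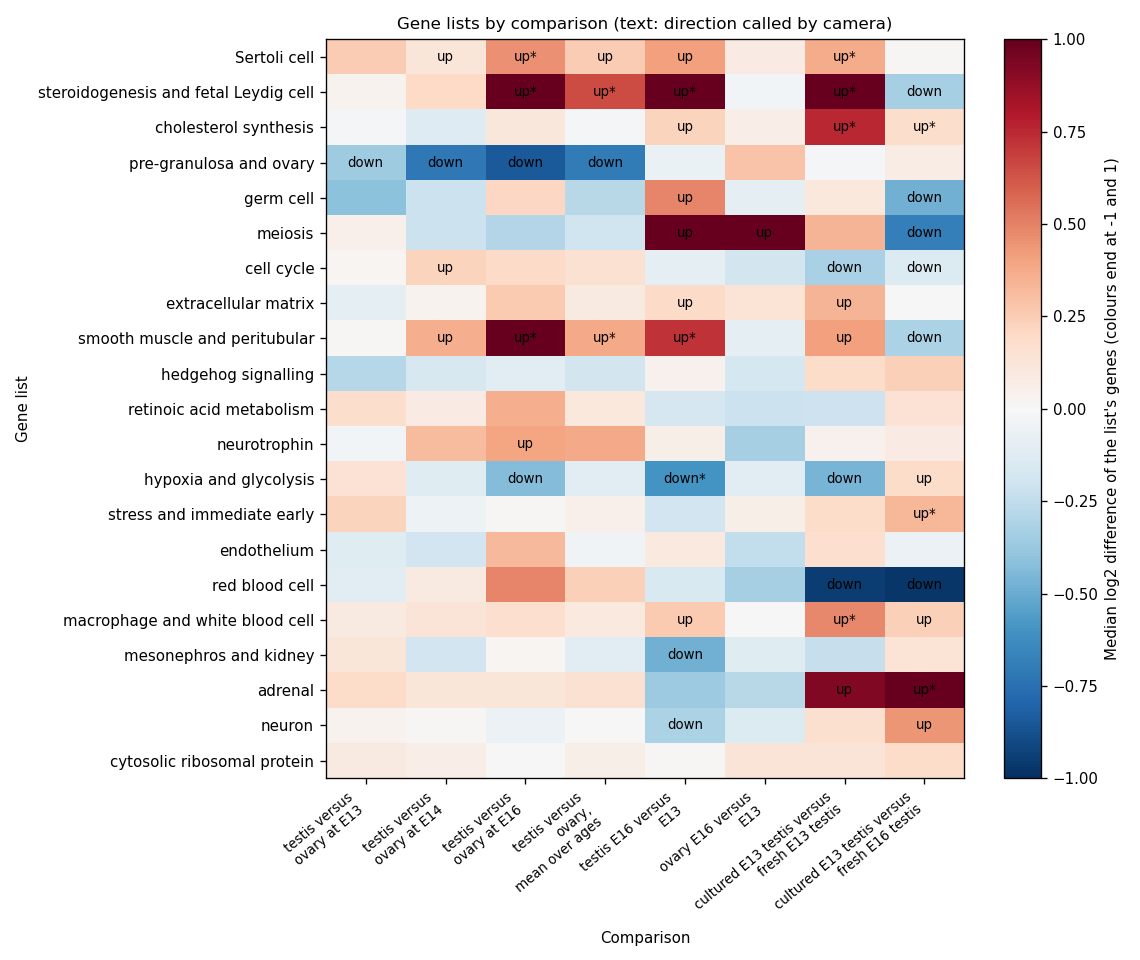
Median log2 difference of the genes of each of the 21 tested lists (vertical) in the 8 main comparisons (horizontal); colours end at -1 and 1. Text gives the direction called by camera at its preset correlation, and a star marks calls that also passed with an estimated correlation. Leydig cell genes were called up with a star in E16 testis against E16 ovary and against E13 testis, and in culture.

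Set against fresh E16 testis of nominally similar age, cultured testis differed in Cpa1, Nppc and adrenal-type enzymes among other genes. Cyp11b1 stood at 262 ± 101 in culture and 13.6 ± 2.4 in E16 testis (SD, n = 2; log2 3.18, adjusted p = 0.000851 by limma), and Cyp21a1 at 148 ± 9.0 against 8.8 ± 1.8 (log2 2.73, adjusted p = 0.00416). Akr1b7, an aldo-keto reductase (log2 2.34), Postn (log2 1.66), the chaperone clusterin Clu (log2 1.18) and Serpina5 (log2 1.14) were higher in culture at an adjusted p of 0.0447 each. Lower in culture were Cpa1 (204 ± 8.0 against 2357 ± 1166, log2 -3.34, adjusted p = 0.00943), the natriuretic peptide Nppc (27.7 ± 8.6 against 184 ± 5.1, log2 -2.21, adjusted p = 0.00125), Ybx2 (log2 -1.67) and the natriuretic peptide receptor Npr3 (log2 -1.21). Probe sets of Stmn2 and Cxcr4 were higher too, while the brightest ones of these genes did not pass.

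Adrenal, stress and cholesterol synthesis genes stood higher in culture than in E16 testis with both correlations. The adrenal list had Cyp11b1 and Cyp21a1 of 6 passing (5 adjusted over the list alone; camera, adjusted p = 1.61e-12, and 0.0192 with an estimated correlation). The stress and immediate early list had 0 of 23 passing (Ier3 and Atf3 adjusted over the list alone; adjusted p = 7.25e-06, and 0.0192 with an estimated correlation), and the cholesterol synthesis list 0 of 17 passing (adjusted p = 5.59e-05, and 0.035 with an estimated correlation). Neuron (adjusted p = 7.25e-06; adjusted p = 0.0588 with an estimated correlation), macrophage (adjusted p = 0.0224; adjusted p = 0.0915 with an estimated correlation) and hypoxia genes (adjusted p = 0.0352; adjusted p = 0.26 with an estimated correlation) were called higher with 0 members passing. Leydig cell (adjusted p = 0.0128; adjusted p = 0.216 with an estimated correlation), germ cell (adjusted p = 0.0234; adjusted p = 0.135 with an estimated correlation) and meiosis genes (adjusted p = 0.000439; adjusted p = 0.0819 with an estimated correlation) were called lower with 0 members passing. So were cell cycle (adjusted p = 0.00314; adjusted p = 0.18 with an estimated correlation), smooth muscle (adjusted p = 0.00637; adjusted p = 0.073 with an estimated correlation) and red blood cell genes (adjusted p = 7.25e-06; adjusted p = 0.18 with an estimated correlation). In all 15 probe sets passed, 11 higher and 4 lower in culture, but this balance depended on the arrays used. Without cultured replicate 1 it was 9 higher and 23 lower, with 8 of the calls shared, and without the 4 arrays with discordant Xist 3 higher and 10 lower, with 4 shared. With chip period as a block 12 passed, 10 of them shared, and Akr1b7, Postn, Clu and Serpina5 no longer passed. An offset of 1 gave 7 calls, the probe sets above the median signal 4. Chip batch as a random block gave 72 calls, 52 higher and 20 lower, with all 15 shared. The count was 32 and 3 without cultured replicates 1 and 2, 6 and 3 without E16 testis replicates 1 and 2, 7 without any E13 or E14 testis array, 5 without any E13 ovary array, 8 without any E14 ovary array and 9 without any E16 ovary array. In these 14 fits Cyp11b1 and Nppc passed each time, but Npr3 lost its call in 14, Clu and Postn in 13, Akr1b7 and Serpina5 in 12, Ybx2 in 10 and Cpa1 and Cyp21a1 in 2.

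The change in culture was then set against the change in vivo from E13 to E16. Of the 112 probe sets that rose in vivo, 68 also rose in culture (1.19 from independent lists), and of the 38 that fell, 23 also fell (0.13 from independent lists); 0 passed in opposite directions. Among the 150 in vivo calls, 98.7% had the same sign in culture, at a median 0.83 of the in vivo change. Across all probe sets, which are not independent replicates, the 2 changes correlated at r = 0.681 (Spearman 0.609) with a covariance of 0.113. Unchanged groups that share the E13 testis arrays gave r = 0.50, Spearman 0.467 and a covariance of 0.046 in simulation, so the covariance exceeded that value by 0.067. That simulation holds no chip batch effects, although the cultured and E16 testis arrays of the same number lay in the same chip batch. With each change taken from its own E13 array, so that the 2 changes shared no array, chip batch or chip period, a split chosen after seeing the data, r was 0.313 and 0.252 and the covariance 0.075 and 0.062. The overlap of calls and the share with the same sign were not split in this way and include the shared E13 arrays.

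**Figure D4:**
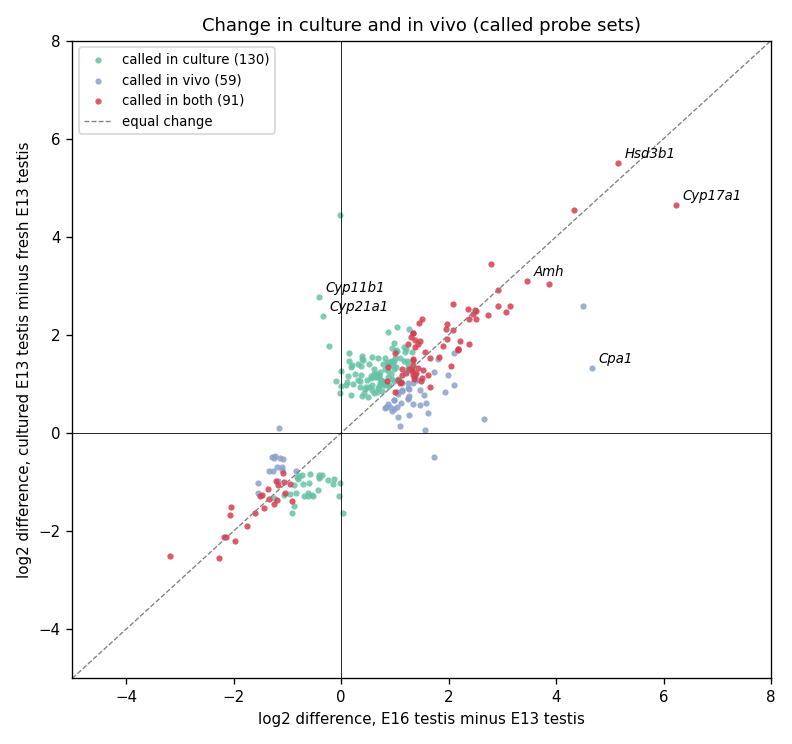
Log2 change in cultured testis (vertical) against log2 change in testis from E13 to E16 (horizontal), both relative to the same E13 testis arrays, for the probe sets that passed in either comparison. Of these 91 passed in both, 130.0 in culture alone and 59 in vivo alone, and none passed in opposite directions.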

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

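The tests in this part were chosen before their results were seen, apart from the count without the 4 arrays with discordant Xist; counts with chip period as a block had been seen before the held-out test was set. The sex difference at E16 differed from that at E13 in 23 probe sets, by limma's test of the difference itself. Larger towards testis at E16, in log2 units, were Cyp17a1 (6.09), Cpa1 (5.91), Hsd3b1 (5.25), Cyp11a1 (3.93), Amh (3.92), Star (3.30, and 3.70 by its other probe set), Tsx (3.00), Jag1 (2.39), Nppc (2.20), Rnf207 (2.02), Npr3 (2.01), Enc1 (1.93), Susd3 (1.73) and 1 probe set without a symbol (1.60). Shifted towards ovary were Rbp4 (-3.12), Mt2A (-2.85), Postn (-2.19), Fbp2 (-2.14), Sry (-2.12), Amhr2 (-1.87), Slc4a4 (-1.52) and Cxcr4, for which the probe set that passed gave -1.76 and the brightest one -1.15. With chip period as a block all but Postn (adjusted p = 0.0726) still passed. Without the 4 arrays with discordant Xist, 0 passed by limma, against 1030 at an unadjusted p under 0.05 in the full set.

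The Jagged ligand Jag1 and the natriuretic peptide Nppc, like Mt2A below chosen after their values were seen, were among the genes that were higher in E16 testis than in any ovary group. Jag1 stood at 118 ± 11.4 (SD, n = 2) in E16 testis, 20.6 ± 10.7 in E13 testis and 21.4 ± 6.9 in E16 ovary. Nppc stood at 184 ± 5.1, 45.2 ± 13.9 and 15.1 ± 0.1 in the same groups, and in cultured testis at 27.7 ± 8.6, while Jag1 rose in culture to 108 (log2 1.77 over E13 testis). Mt2A moved in opposite directions in the sexes, from 534 ± 45.5 to 169 ± 53.2 in testis and from 592 ± 44.0 to 1429.8 ± 54.1 in ovary.

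The control probe set for 5S ribosomal RNA, which enters no gene comparison, read 1231 in E16 ovary replicate 1 and 24 to 289 in the other arrays. The same array had the highest 3′ to 5′ ratios of actin (3.34) and GAPDH (1.75).

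The difference between the sexes over the ages, 366 probe sets, was weighed against chance and against chip period, since 4 of the 6 ovary arrays belong to a period with 1 testis array. Of 108 distinct ways to split the 12 arrays into 2 sexes within each age, 100 were drawn. Of these, 1 (the real split) gave 366 or more calls, and the highest of the others gave 117. That split held 1 array of chip period 3 in its first group, as did the real one. Most other splits mix testis and ovary arrays within groups, which widens the estimated spread and lowers counts by construction. The real split thus gave the most calls of those drawn, but this cannot exclude chance. The probe sets were then ranked on 10 arrays and checked in 4 held-out arrays that pair testis and ovary within a chip batch. Of the top 366, 81.1% (77 to 85) kept their direction there, against 61.3% of all probe sets. This interval comes from resampling probe sets, which are not independent, and does not measure spread between pools. The rule set beforehand for excluding chip period asked for a minimum share that kept direction. The lower end of the interval, 77%, fell short of that share. The rule also asked for a median size above 0.5 of that in the ranking. Their median size in the held-out arrays was 0.41 of it, so this part was not met either. Probe sets picked for a small p shrink in other arrays even without a chip period effect. The ranking also averaged E13, E14 and E16, while the held-out arrays were of E14 and E16. The ratio alone thus cannot show a chip period effect. A part of the sizes or calls may still come from chip period and cannot be told apart from sex here. With chip period as a block 219 passed, of which 150 were among the 366.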

How the results depend on the processing

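The tests without the 4 arrays with discordant Xist and with separate E13 testis arrays were chosen after seeing the data. Quantile normalization and an intensity-dependent prior left each of the 13 counts within 1.5 times its value. Of 2672 results for named genes under the alternatives, 2209 kept direction and significance, 463 kept direction alone and 0 reversed. Of the losses, 326 came from leaving out an array, 86 from leaving out the 4 arrays and 32 from the offset of 1. Fewer arrays lower the power by construction; for the other changes the cause was not tested. Dim genes are limited by signal over background, which the offset damps.

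With an offset of 1, the counts were 11 for testis against ovary at E14, 167 at E16, 8 for the change of the sex difference, 7 for testis E14 against E13, 7 for E16 against E14, 94 for E16 against E13, 3 for ovary E14 against E13, 60 for ovary E16 against E13, and 106 and 7 for cultured against fresh E13 and E16 testis. Among probe sets above the median signal, 0 passed at E13 between the sexes (limma, 1236 at an unadjusted p under 0.05 among all) and 4 for cultured against E16 testis.

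With chip period as a block, the counts were 35 between the sexes at E14, 219 over the ages, 46 for the change of the sex difference, 36, 31 and 252 for the testis steps E13 to E14, E14 to E16 and E13 to E16, 2 and 1 for the ovary steps E13 to E14 and E14 to E16, and 378 for cultured against E13 testis. With chip batch as a random block (consensus correlation 0.38), they were 93 at E14, 594 at E16, 45 for the change of the sex difference, 20 and 30 for the 2 short testis steps, 1 for ovary E16 against E14 and 72 for cultured against E16 testis. Without the 4 arrays with discordant Xist, they were 0, 0, 14 and 48 between the sexes at E13, E14, E16 and over the ages, 0 for the change of the sex difference, 0, 4 and 6 for the testis steps, 0 for ovary E16 against E13 and 5 for cultured against E13 testis (limma; the unadjusted counts given with each comparison are those of all arrays), and the correlation of culture with in vivo change was 0.591. With separate E13 testis arrays this correlation was 0.313 and 0.252; single arrays and the absence of a shared group both lower it by construction.

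Same-numbered arrays deviated together in part: of 21 pairs of groups, 15 had deviations that correlated above 0.1 (range -0.05 to 0.53). The 6 other pairs were those with E13 ovary. The numbers run partly along the inferred chip batches and periods (replicate 2 lay in chip period 1 in 6 of 7 groups). The labels name no source that a number marks, so the numbers were not treated as pairing the samples. A pairing along chip batch or period was not excluded. The fit with the replicate number as a block gave 36 calls between the sexes at E14, 673 over the ages, 18 for testis E14 against E13 and 276 for ovary E16 against E13, and left the other counts within 1.5 times.

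Leaving out each array in turn gave 0 to 2 calls between the sexes at E13, 1 to 32 at E14, 62 to 307 at E16 and 146 to 815 over the ages, 2 to 20 for the change of the sex difference, 0 to 12, 7 to 22 and 22 to 155 for the testis steps E13 to E14, E14 to E16 and E13 to E16, 0 to 0, 0 to 1 and 8 to 145 for the same ovary steps, 49 to 211 for cultured against E13 testis and 3 to 32 against E16 testis; the arrays that lowered a count most are named with each comparison. The correlation of culture with in vivo change ranged from 0.535 without cultured replicate 1 to 0.763 without E13 testis replicate 2. Of 168 gene list tests 49 were called, 44 to 57 with an array left out and 15 with an estimated correlation; fry also called 35 of the 49.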

Other observations

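The tests on Xist and chip batch and both tests on the adrenal-type enzymes were chosen after the result was seen; the test on ovarian RNA was not. The genes in the first 3 paragraphs were chosen after their values were seen. Mean signals of 2 globin genes differed between the ages, with wide spreads between arrays. Hbz, an embryonic alpha-type globin, stood at 2728 ± 227 (SD, n = 2) in E13 testis and 765 ± 596 in E16 testis, and at 2952 ± 75.7 and 535 ± 515 in ovary. Hbb, of the adult beta-globin family, stood at 83.3 ± 45.3 and 5725 ± 1879 in testis and at 106 ± 10.8 and 4734 ± 1119.6 in ovary. Each E16 array (3943 to 7053) read higher for Hbb than each E13 array (51.3 to 115). None of these changes passed over all probe sets (limma, adjusted p = 0.572 and 0.114 in testis, 0.379 and 0.162 in ovary), where the shared estimate of the spread includes the cultured arrays at 2421 and 13. Adjusted over the list alone, Hbb was higher at E16 in both sexes.

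Some probe sets passed in the same direction in testis and ovary between E13 and E16, 14 upwards and 10 downwards. Mgp rose by log2 4.33 in testis and 4.52 in ovary, Enpep by 3.06 and 2.27 and Col6a3 by 2.21 and 2.22. Hoxa5, a positional gene of the trunk, changed by log2 -2.05 and -1.68, Cga by -1.46 and -1.61, and Crabp1, a retinoic acid-binding protein gene, by -1.17 and -0.98. None of these genes was among the 23 probe sets whose sex difference changed between E13 and E16.

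The probe set of Angel2 read 7.2 and 8.3 in the E13 testis arrays and 47.9 to 91.3 in the 12 other arrays, cultured E13 testis included.

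Xist read 269 in E14 testis replicate 1 and 151 in cultured replicate 1, near the level of some ovary arrays. In E14 replicates 1 and 2 the ovary-side genes Fst (120.2 and 39.5) and Wnt4 (98.7 and 72.7) were higher in replicate 1, and so was the testis gene Amh (760 and 477). Wnt4 was also higher in replicate 1 at E16 (77.0 and 49.4), where Xist was low in both testis arrays and Fst was alike (51.7 and 52.1). The Wnt4 gap was thus not particular to the arrays with Xist signal. With E14 ovary replicate 1 (Xist 672) as the source, a mix would need 39.9% ovarian RNA in the E14 pool. It should then raise the 70 ovary-high genes by a median log2 of 0.50 (0.39 to 0.69). This interval and the next come from resampling genes and do not measure spread between pools. E14 ovary replicate 2 read 224, below the 269 of the testis array, so from that source no share would reach it. The share, the predicted rise and the bound below all rest on the choice of replicate 1. The measured excess was 0.27 (0.11 to 0.34) with 46 of the 70 higher in replicate 1, less than such a mix predicts but above the bound of 0.25 set beforehand for excluding it, so ovarian RNA may explain part of the signal and stays open. Chip batch stays open as well: cultured replicate 1 (151) was in the same batch and E16 testis replicate 1 of that batch read 3.3, which met the first criterion for excluding it (1 such array under 16), but this was made stricter after the result was known, since a single array decides little. The low Xist of E16 ovary replicate 2 (12.8) was covered by neither test. In each group with 1 array in chip period 1, that array had the lower Xist, in both sexes. It read 1.9 against 269 in E14 testis, 4.8 against 151 in culture and 1.9 against 36.2 in E13 testis. In E16 testis it read 1.5 against 3.3, in E14 ovary 224 against 672 and in E16 ovary 12.8 against 152. Wnt4 was lower in the chip period 1 array of each of these groups too, with 88.6 against 356 in E14 ovary and 87.5 against 411 in E16 ovary. Whether chip period accounts for these patterns was not tested, and no biological explanation was tested.

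Cyp11b1 and Cyp21a1 were higher in cultured testis than in fresh E13 or E16 testis, and the highest reading of either in any fresh array was 27.6. Cross-hybridisation with the related Leydig cell enzymes is argued against, since both stood well above E16 testis (log2 3.18 and 2.73) where Cyp17a1 was not lower (log2 -1.58 in culture minus E16). Adrenal tissue in the cultured pools could not be excluded: 0 of 4 chromaffin cell genes passed against E13 testis (limma, adjusted p = 0.507 for Th, 0.323 for Dbh, 0.849 for Pnmt and 0.149 for Chga), but their differences were all positive (log2 0.58, 1.12, 0.26 and 0.72). Their cultured means (99.3 ± 16.5, 43.6 ± 40.2, 59.7 ± 26.7 and 18.1 ± 11.1) exceeded the highest fresh arrays (63.8, 20.3, 51.7 and 5.3). Adjusted over the adrenal list alone, 4 genes were higher than in E13 testis, so chromaffin genes were among them. A response of the testis to culture may also account for the higher Cyp11b1 and Cyp21a1. The design names culture as the difference, and no test here separated it from adrenal tissue. Such tissue could also have added to the rise of Hsd3b1, Cyp11a1, Star and Fdx1 in culture.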
